A study of Mus musculus with 6 samples.

How the data were processed

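ATAC-seq was performed on mouse gastric organoids of 2 engineered genotypes, with 3 libraries each. Per the labels' protocols, nuclei were taken from counted organoid cells, tagged with a kit transposase and amplified by PCR before Illumina sequencing. The submitters' processing notes name Bowtie2, Picard, SAMtools, deepTools, MACS3, ChIPseeker and DESeq2, with neither versions nor roles, and the genome build mm10. How reads were aligned, shifted for the transposase, filtered for duplicates or mitochondrial DNA, and which peak threshold was set, is not given in the sources used here. These choices can move the number and the width of peaks.

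The deposited files were a peak list for each library, without header, in the column order of the narrowPeak format. Peaks were called per library and not on pooled samples, since each list belongs to a single sample. The columns were start and end on mm10, the offset of the summit, and the authors' peak score, a whole number whose scale is not stated. The fold enrichment, p-value and q-value columns, 3 in each list, held 0 throughout the deposited lists and were not used. Scores under 200 fell on evenly spaced steps of 5.74 to 6.81 units in all libraries, as a scaled count of overlapping fragments would, and the median peak was 17.9 to 27.9 steps high. Peak ends, and nearly all starts, were multiples of 10 bp. Read depth per library is unknown from these lists, so no counting interval for a peak is given. A peak absent from a list was under the authors' threshold and its region need not be closed. Intervals printed for shares of regions cover counting error only.

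Peaks on chromosomes 1 to 19, X and Y of the 6 lists were merged where they overlapped by at least 1 bp, and each region was marked as present in the libraries whose peaks it held. The 99 to 124 peaks per library on other sequences were left out. Regions were called TP-only, TPA-only or common as defined in the results. Genes came from a RefSeq table of GRCm38.p6, which has the coordinates of mm10, with 21887 protein-coding genes and no strand. For this reason the planned promoter share was replaced by the share within 1 kb of either end of a protein-coding gene, called a gene edge, with 3 kb as an alternative. The distance was taken from the mean summit of a region, or from the summit of a single peak. A wide region can therefore cover a gene end and not count as a gene edge. A region was assigned to the gene whose body held its mean summit, or else to the nearest gene within 100 kb, in place of the planned nearest transcription start site. No genome sequence was used here, so the planned motif comparisons were not run.

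Numbers per library were compared by exact two-sided permutation tests of the difference of means, whose smallest p with 3 against 3 libraries is 0.1. Counts of TP-only and TPA-only regions and the Jaccard index by base pairs were set against the other 9 of the 10 splits of the libraries. Shares at gene edges and on chromosomes were compared by Fisher's exact test over regions with Woolf intervals. Of the score, only order and contrasts within a list were used: rank percentiles, and log2 medians of common regions at gene edges or on a chromosome relative to the same library's median. The contrast of scores at gene edges and the comparison of chromosomes were chosen after seeing the data. Chromosome values were first taken relative to a single median per library. After these were seen they were taken relative to the library's median for the same kind of place, gene edge or elsewhere, because scores at gene edges differed between genotypes genome-wide, and the single median was kept as an alternative. For 26 fixed gene lists, the share of a list's assigned regions in each class was compared with 10000 random lists of genes matched on the number of regions, with Benjamini-Hochberg adjustment over 52 tests. The smallest two-sided p that these draws can give is 0.0002. The lists cover mucins and trefoil or gastrokine peptides, mucin O-glycosylation, mucin granule exocytosis, secretory factors, markers of pit, neck and SPEM, chief, parietal, endocrine, stem and isthmus, intestinal, squamous and basal, fibroblast, immune and endothelial cells, foregut and gastric transcription factors, epithelial junctions, mesenchymal transition, Wnt, YAP and TEAD, AP-1 and p53 targets, BAF and PBAF subunits, PI3K, AKT and mTOR genes, interferon and antigen presentation, and housekeeping genes.

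The region classes, the comparison of region counts and of the Jaccard index with other splits, the gene lists and the rule for named genes were chosen before the data were examined. The rule took the 3 engineered genes, up to 2 genes of each list with the largest difference between their numbers of TP-only and TPA-only regions, the 5 genes with the largest surplus of each class, the 5 best-ranked regions of each class, and Muc5ac, Muc6 and Cdh1. The calling of regions and the list test were tested on simulated data. With 6 simulated libraries and 162313 regions, 98.5% of 200 planted TP-only and 95.5% of 200 planted TPA-only regions were recovered. The planted regions were common regions set to present in all libraries of a single genotype and in none of the other. Their recovery therefore checks the merging and calling, not the power to find a real difference. A further 1026 and 809 regions were called with no planted effect. For the list test the merged regions were marked at random, and 5.5% of 200 random lists without effect had p under 0.05. The marks were set independently, without the high counts at single genes seen in the data. Alternatives covered the overlap rule, fixed windows of 500 bp, stricter score thresholds, equal list lengths, other presence rules, autosomes only, backgrounds matched on width or score rank, other gene distances, sign flips within same-numbered libraries and leaving out each library. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.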

Results

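Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse gastric organoids, three-dimensional cultures of stomach epithelium. All organoids lacked Trp53, which encodes the tumour suppressor p53, and carried the Cas9 nuclease. In the TP organoids a guide RNA had been directed at Pten, a phosphatase that opposes PI3K signalling. The TPA organoids had received a further guide against Arid1a, a subunit of the BAF (SWI/SNF) chromatin remodelling complex. There were 3 libraries of each genotype, numbered 1 to 3 in the labels. Nothing in the labels says that they came from separate cultures or animals, so p-values from comparisons of libraries measure only the spread between these samples, which may be technical. Tests over regions and tests against random gene lists hold no spread between libraries at all. The comparison addresses how chromatin differs once Arid1a is also disrupted, in a study concerned with gastric mucin and signet ring cell carcinoma. If each genotype was a single culture, it cannot separate Arid1a disruption from other differences between the cultures. The deposited lists held 110253, 109687 and 102339 peaks for TP replicates 1 to 3 and 92597, 96531 and 112583 for TPA replicates 1 to 3. Read depth is unknown from these lists. A TP-only region below is a merged region with a peak in all 3 TP libraries and in no TPA library, a TPA-only region is the converse, and a common region has a peak in all 6 libraries.

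The chromatin of the engineered genes was open in both genotypes. Arid1a (chromosome 4, 133679008 to 133756769, mm10) had 5 common regions, among them one at a gene edge at 133756201 to 133757760, and no TP-only or TPA-only region. Pten (chromosome 19, 32757577 to 32826160) had 2 common regions, including one at its edge at 32755431 to 32759100, and likewise no region of either class. Trp53 (chromosome 11, 69580348 to 69591873) had 2 common regions and 1 TPA-only region in the gene body, at 69585111 to 69585340. Peaks at Arid1a and Pten do not check the edits, because a small deletion in an exon need not alter accessibility. For Trp53 the sample titles give a null genotype and not the part removed, so its peaks were not read as a check either.

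Many regions had peaks in a single genotype. Of 198640 merged regions, 7801 were TP-only, 4800 were TPA-only and 32846 were common, and 93868 had a peak in a single library. No region can pass a threshold of 0.05 by itself with 3 libraries against 3, for which the smallest exact two-sided p is 0.1, so the counts were set against the other 9 splits of the 6 libraries. The genotype split gave 12601 regions in all, and the highest of the other splits gave 2049. The numbers depended on how presence was defined: with at least 2 of 3 libraries against none they were 18415 and 13534, with at most 1 library of the other genotype 12064 and 7321, and with the holding group's peaks all in the better 50% of their lists 2006 and 1096. Without TP replicate 3 the TP-only count was 15560, and without TPA replicate 1 the TPA-only count was 10466 against 8419 TP-only regions, though this asks for 2 TPA libraries against 3 TP libraries. With both TP replicate 3 and TPA replicate 1 left out, and so 2 libraries of each genotype, TP-only regions were the more numerous, at 16616 against 11123.

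**Figure D1:**
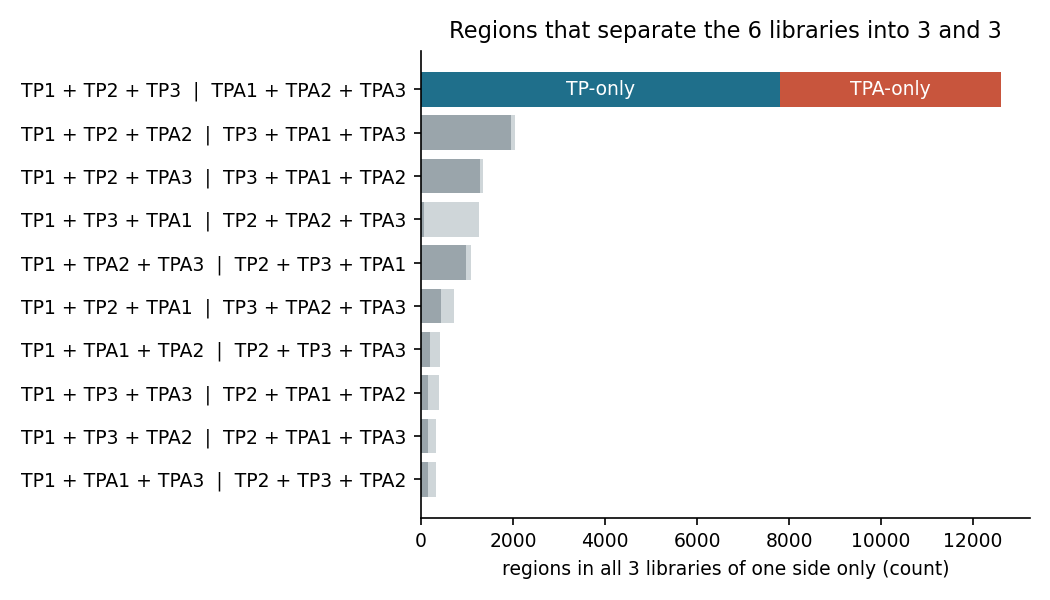
Bars give the number of merged regions with a peak in all 3 libraries of one side and in none of the other, for each of the 10 splits of the 6 libraries into 3 and 3. The genotype split (7801 TP-only and 4800 TPA-only regions) stands above the highest other split, at 2049.

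Some genes held many regions of a single class. Samd5 (chromosome 10, 9262461 to 9675926), which encodes a sterile alpha motif protein, led with 24 TP-only and 0 TPA-only regions, of which 21 lay in the gene body and 3 outside it. Next came Macrod2, an ADP-ribosyl hydrolase gene, with 20 and 0, the stress-activated kinase gene Map3k20 with 19 and 0, Cd93, which encodes a C-type lectin-like receptor, with 18 and 0, and Gas7 with 13 and 0. Between the first and the last TP-only region at each gene, a TPA library had a peak in 1 of 46 regions at Samd5, 36 of 104 at Macrod2, 13 of 65 at Map3k20, 3 of 31 at Cd93 and 1 of 25 at Gas7. The single region at Samd5 and at Gas7 was common, whereas none was common at Cd93. Macrod2, Map3k20 and Cd93 lie on chromosome 2, where the scores of common regions were also lower in TPA (log2 change -0.30, below). At the other end were Mecom, which encodes the transcription factor EVI1, with 2 TP-only and 12 TPA-only regions, the phospholipase gene Plcb1 with 0 and 9, the endocytic adaptor gene Sh3kbp1 with 0 and 9, Itm2b with 0 and 8, and Ext1, a heparan sulphate polymerase gene, with 0 and 7. Mecom lies on chromosome 3 and Sh3kbp1 on chromosome X, whose common regions scored higher in TPA (log2 change 0.66 and 0.21), whereas Plcb1 lies on chromosome 2. Ext1 lies on chromosome 15, where the change was 0.17. Among 17770 genes with an assigned region, 3030 had TP-only regions alone, 2380 had TPA-only regions alone and 873 had both. There were 221 genes with 5 or more TP-only regions and 53 with 5 or more TPA-only regions.

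**Figure D2:**
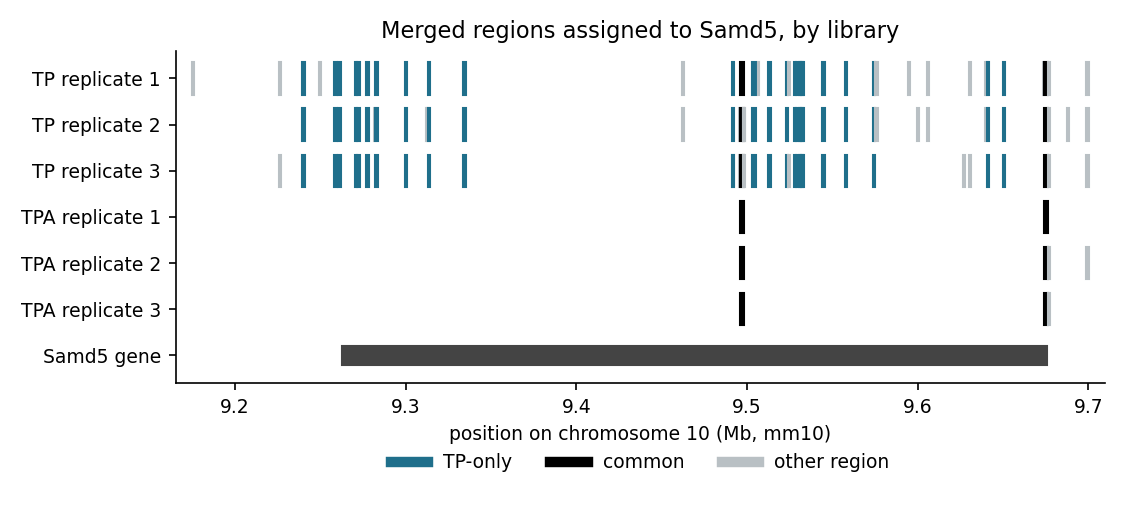
Merged regions assigned to Samd5 are drawn by library against position on chromosome 10 (Mb, mm10), with TP-only regions in blue, common regions in black, other regions in grey and the gene as a dark bar; each region is widened by 1 kb for visibility. All 24 TP-only regions appear in the TP rows alone, and the 2 common regions appear in every row.

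The 5 highest-scoring regions of each class lay away from gene edges, as did most regions of both classes. Of all TP-only regions 4.59% lay at a gene edge, and of all TPA-only regions 15.1%. By mean rank percentile of the authors' peak score within the lists that held them, the leading TP-only region lay on chromosome 15 at 61913151 to 61914290, an intergenic position 71550 bp from Myc, a growth-promoting transcription factor gene, at percentile 99.3. It was followed by regions in the bodies of Rnf144b (chromosome 13, 47244521 to 47245440, 98.3) and Mcc (chromosome 18, 44472401 to 44473910, also 98.3), an intergenic region nearest to Rpl37a (chromosome 1, 72738831 to 72740260, 97.9) and one in the body of Cobl (chromosome 11, 12420991 to 12421860, 97.6). Of the TPA-only regions, the first was intergenic on chromosome 12 at 20814841 to 20816260, 145135 bp from LOC108167368, at percentile 98.0. The next lay 21364 bp from Aldh1a3, which encodes a retinaldehyde dehydrogenase (chromosome 7, 66448011 to 66449490, 94.6), in the body of the potassium channel gene Kcnma1 (chromosome 14, 23307641 to 23310570, 94.2), in the body of Smoc1 (chromosome 12, 81156281 to 81158920, 93.3) and in the body of Mrps28 (chromosome 3, 8865721 to 8866770, 93.2).

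TP-only regions lay at gene edges less often than TPA-only regions, though another split of the libraries, with far fewer regions, gave nearly the same ratio. A gene edge here is a position within 1 kb of either end of a protein-coding gene, since the annotation used gives no strand. Each region was placed by its mean summit, so a wide region can cover a gene end without counting. This was so at Actb (chromosome 5, 142903561 to 142908860), with its mean summit 2034 bp from the nearest edge. Wider regions are more exposed to this: the median width was 980 bp for common, 320 bp for TP-only and 290 bp for TPA-only regions. Of the TP-only regions 358 lay at a gene edge, a share of 4.59% (95% Wilson interval 4.15 to 5.08), against 726 of the TPA-only regions, or 15.1% (14.1 to 16.2), and 9411 of the common regions, or 28.7% (28.2 to 29.1). The odds of a gene edge were 0.270 times as high for TP-only as for TPA-only regions (95% interval 0.236 to 0.308, Fisher's exact test over regions, two-sided, p = 3.2e-90), 0.120 times as high for TP-only as for common regions (0.107 to 0.134) and 0.444 times as high for TPA-only as for common regions (0.409 to 0.482, p = 1.3e-95). Regions are not replicates, and other splits gave ratios of the same order: their 18 sides had odds ratios of 0.119 to 0.498 against common regions, and the ratio between sides reached 0.271 where TP replicate 3, TPA replicate 1 and TPA replicate 3 formed a side. That side held 102 regions, 16.7% of them at gene edges, against 1947 on the other side. It joins the libraries with the highest gene-edge shares of peaks, TP replicate 3 (22.4%) and TPA replicate 1 (22.6%), against 15.0% to 17.1% in the rest. The comparisons with common regions also depended on the background, and common regions are wider and score higher. Against common regions of matched width the ratio was 0.466 for TP-only and 2.03 for TPA-only regions, and against common regions of matched score rank 0.386 and 1.28, so that the TPA-only ratio turned from below 1 to above it.

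Scores at gene edges were also compared with those elsewhere within the common regions of each library. The median summit score at gene edges was 1.46 ± 0.04 times that of the other common regions in TP (SD, n = 3) and 2.69 ± 0.05 times in TPA (SD, n = 3). On the log2 scale the contrast was 0.55 ± 0.04 and 1.43 ± 0.03, a difference of 0.88, and the highest TP library (0.59) lay below the lowest TPA library (1.40). This gave an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 allows. Against other common regions of matched width, the contrast turned below 0 in TP, at -0.21 ± 0.04, and was 0.56 ± 0.03 in TPA (SD, n = 3). In ranks among the common regions, the median gene-edge region stood at percentile 60.5 ± 1.03 in TP and 74.3 ± 0.61 in TPA (SD, n = 3, exact p = 0.1).

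**Figure D3:**
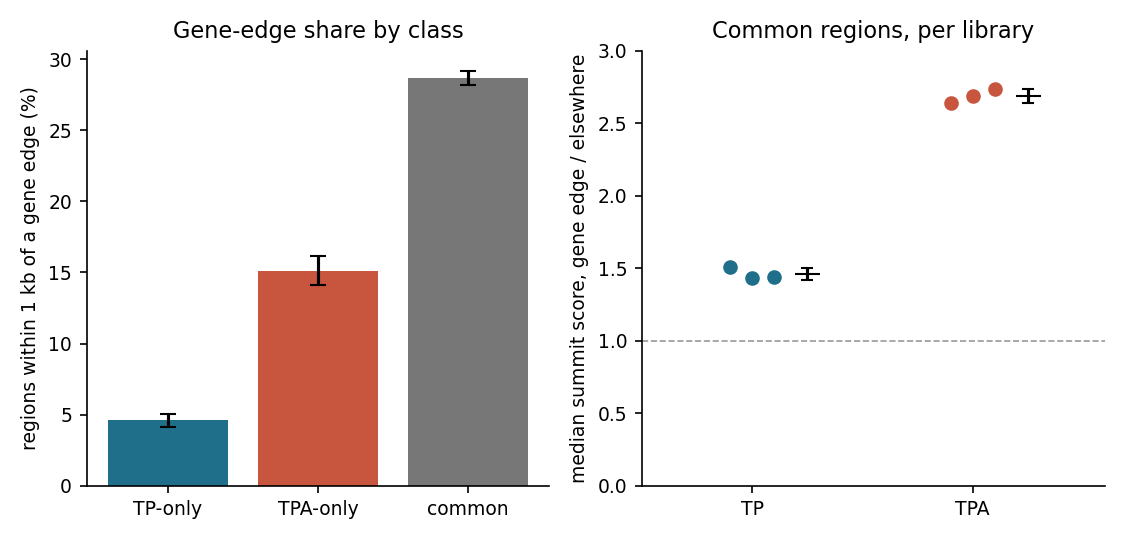
Left, the share of regions with a mean summit within 1 kb of either end of a protein-coding gene (%) for TP-only, TPA-only and common regions, with 95% Wilson intervals as bars. Right, the median summit score at gene edges divided by that elsewhere in common regions, as a point for each library with the mean and SD beside; TP libraries sit between 1.43 and 1.51 and TPA libraries between 2.64 and 2.74.

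Regions of a single class were found at 5 of the 16 gastric mucin, trefoil and gastrokine genes with a region. For all 17770 genes with a region, 3030 had TP-only regions alone, 2380 TPA-only alone and 873 both. Over all assigned regions 3.77% were TP-only and 2.41% TPA-only. The counts for single genes given here and below are not set against the gene's number of regions, which was 97 at Cd44 and 75 at Irs2. Muc5ac, the main mucin of gastric surface cells, had 0 TP-only and 0 TPA-only regions. The region at its edge (chromosome 7, 141788761 to 141788980) had a peak in TP replicates 1 to 3 and in TPA replicate 3. Muc6, the mucin of gland cells, had 0 and 0. In this list Muc15, on chromosome 2, had 1 TP-only region and Muc1, Muc16, Muc20 and Gkn3 had 1 TPA-only region each, and 11 had none. The TPA-only region of Muc1, which encodes a membrane mucin, lay at its gene edge on chromosome 3 (89228841 to 89229100). Of 22 mucin O-glycosylation genes, 5 had TP-only regions alone, 2 had TPA-only regions alone, 2 had both and 13 had neither. The sialyltransferase gene St3gal1 had 8 TP-only and 0 TPA-only regions and Galnt2, which starts O-glycan chains, had 2 and 5. Of 30 genes of granule exocytosis, 8 had TP-only regions alone, 5 TPA-only alone, 1 both and 16 neither, with Nsf and Syt1, of the membrane fusion machinery, at 3 and 0 each. Of 12 secretory differentiation and ER export factors, 3 had TP-only regions alone and 4 TPA-only regions alone. Klf4, a zinc-finger factor of differentiated epithelium, had 0 TP-only and 4 TPA-only regions, 1 of them at its gene edge, and Ern1, the sensor kinase of the unfolded protein response, had 3 and 0.

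Marker genes of the gastric cell types were split between the classes. Among 11 pit cell markers with a region, Tspan8 and Mucl3 had 1 TP-only region each and Fer1l6 had 2 TPA-only regions. Of 11 neck and SPEM markers, Cd44, a hyaluronan receptor on chromosome 2, had 8 TP-only and 1 TPA-only regions, whereas the chemokine gene Cxcl17 had 0 and 3. The 6 chief cell markers with a region included 3 with TPA-only regions, namely Rab26 and Rnf43 with 2 each and Bhlha15 with 1, and none with TP-only regions. Of 11 parietal cell markers, Esrrg had 3 TP-only regions and Car2, on chromosome 3, had 2 TPA-only regions. Neurod1 and Nkx2-2, both on chromosome 2, were the only ones of 11 endocrine markers with a region of either class, 1 TPA-only region each. Of 12 stem and isthmus markers, 3 had TP-only regions alone, 2 TPA-only alone and 2 both; Lgr5, a Wnt-responsive stem cell receptor, had 3 and 0 and Lrig1 had 0 and 2. Among 15 intestinal markers, Vil1, Fabp1 and Krt20 had 1 TPA-only region each. Of 19 foregut and gastric transcription factors, 3 had TP-only regions alone, 5 TPA-only alone and 3 both, with Gata4 at 2 and 0. Of 11 squamous and basal markers, 4 had TP-only regions alone; Trp63, the p63 gene, had 6 and 2, and the keratin gene Krt15 had 0 and 4. Bhlha15, Tspan8, Vil1, Muc15, Muc16 and Muc20 fall outside the rule for named genes and were chosen after their values were seen.

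Genes of epithelial structure and signalling likewise held both classes. Of 16 epithelial junction genes, 7 had TP-only regions alone, 3 TPA-only alone and 2 both. Cdh1, the E-cadherin gene, had 15 common, 2 TP-only and 1 TPA-only regions, Epcam had 0 TP-only and 4 TPA-only, and the keratin gene Krt19 had 0 and 3. Of 17 mesenchymal transition genes, 5 had TP-only regions alone and 4 TPA-only alone, with the gelatinase gene Mmp2 at 4 and 0 and Tgfb2 at 3 and 0. Of 27 PI3K, AKT and mTOR genes, 7 had TP-only regions alone, 5 TPA-only alone and 4 both. The insulin receptor substrate gene Irs2 had 10 TP-only and 0 TPA-only regions and Rptor, a subunit of mTORC1, had 6 and 0. Of 14 Wnt target genes, 5 had TP-only regions alone and 3 TPA-only alone, Myc having 2 and 0. Of 15 YAP and TEAD targets, 5, 2 and 3 had TP-only, TPA-only and both, with Cdc42ep3 at 3 and 1 and Axl at 2 and 0. Of 13 AP-1 genes, 4, 2 and 2 did, with Atf3 at 3 and 0 and Fos at 3 and 1. Of 14 p53 targets, 3 had TP-only regions alone and 2 TPA-only alone, the desmosomal gene Perp having 4 and 0 and Bax 0 and 1. Of 28 BAF and PBAF subunit genes, 23 had neither class; Bicra had 2 and 0 and Arid1b, the paralogue of Arid1a, had 2 and 1. Of 15 interferon and antigen presentation genes, 4 had TPA-only regions alone and 2 had both, with Irf1 at 1 TP-only and 4 TPA-only regions and the class I gene H2-D1 at 0 and 2.

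Markers of cells other than epithelium held regions of both classes. Of 6 fibroblast markers with a region, Col1a1 had 1 TPA-only and Thy1 1 TP-only region. Of 9 immune markers, Cd74 had 2 TPA-only regions, Itgam had 1 TP-only region and Csf1r had 1 of each. Of 8 endothelial markers, 4 had TPA-only regions, led by Kdr with 3 and Cdh5 with 1, and none had TP-only regions. Of 12 housekeeping genes, 2 had TP-only regions alone, 2 TPA-only alone and 2 both, with Ywhaz at 2 and 1 and Actb at 0 and 1. Csf1r was also chosen after its values were seen.

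No fixed list held more or fewer regions of a class than random lists after correction. Each list's share of TP-only or TPA-only regions was compared with 10000 random gene lists matched on regions per gene, and 0 of 52 tests passed a Benjamini-Hochberg adjusted p of 0.05. There were 3 at an unadjusted permutation p under 0.05. Interferon and antigen presentation genes had 10 TPA-only regions among 114, or 8.77% against a median of 2.38% in random lists (permutation p = 0.0074, adjusted p = 0.385). Chief cell markers had 5 among 51, or 9.80% against 2.00% (permutation p = 0.018, adjusted p = 0.468). BAF and PBAF subunit genes had 5 TP-only regions among 368, or 1.36% against 3.68% (permutation p = 0.036, adjusted p = 0.631). When the merged regions were marked at random, 19 of 20 lists planted at 3 times the background rate had an unadjusted permutation p under 0.05. In the data some genes held many regions of a class, such as 24 TP-only among 53 regions at Samd5 and 18 among 34 at Cd93. Marks set independently do not copy this, so recovery in the data may be lower. Recovery at the adjusted threshold was not simulated either, so a list with a raised share could be missed here.

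Chromosome 3 stood apart from the other autosomes. It held 160 TP-only and 445 TPA-only regions, so that 73.6% of its regions of either class were TPA-only, against 26.6% to 49.8% on each of the other autosomes. The odds of TPA-only over TP-only were 4.88 times as high on chromosome 3 as elsewhere (95% interval 4.06 to 5.87, Fisher's exact test over regions, adjusted p = 3.2e-72), and 8 chromosomes passed an adjusted p of 0.05. Among these the odds were also raised on chromosome 15 (1.51), which holds Ext1, and on chromosome 17 (1.65), which holds Epcam, H2-D1 and Rab26. They were lowered on chromosomes 1, 2, 8, 12 and 16. Common regions on chromosome 3 scored -0.50 ± 0.003 (SD, n = 3) on the log2 scale in TP, relative to each library's own median for the same kind of place, and 0.16 ± 0.02 (SD, n = 3) in TPA, a difference of 0.66 (exact p = 0.1, the smallest possible). On chromosome 2 the values were 0.22 ± 0.02 and -0.09 ± 0.02, a difference of -0.30 (SD, n = 3, exact p = 0.1), which was -0.19 without TP replicate 3 and TPA replicate 1. On chromosome X they were -0.49 ± 0.01 and -0.28 ± 0.02, a difference of 0.21 (SD, n = 3, exact p = 0.1), which was 0.08 without that pair of libraries, 0.12 without TPA replicate 1 alone and 0.44 when all common regions of a library shared a single centre. The other autosomes lay between -0.17 and 0.17. The widest difference was on chromosome Y, with 9 common regions, at -1.74 ± 0.19 in TP and 0.14 ± 0.14 in TPA, a difference of 1.88 (SD, n = 3, exact p = 0.1). It was not shared by all of them, at 0.15 for the 3 at gene edges and 2.33 for the 6 elsewhere.

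**Figure D4:**
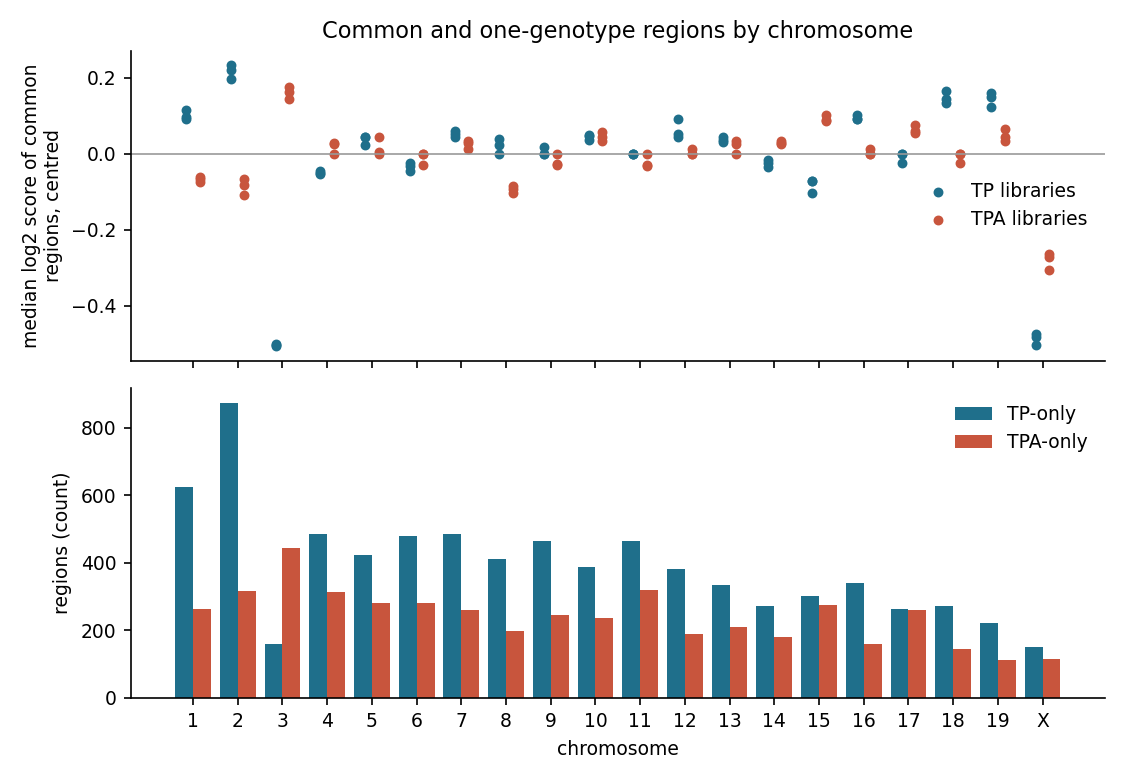
Top, the median log2 score of common regions on each autosome and on X, relative to each library's own medians for gene-edge and other regions, as a point for each library (blue TP, red TPA). Bottom, the number of TP-only and TPA-only regions on these chromosomes (Y, with 9 common regions, is not drawn); chromosome 3 alone among the autosomes has more TPA-only (445) than TP-only (160) regions.

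Peak lists were more alike within than between genotypes on average, but not for each pair of libraries. The Jaccard index by base pairs averaged 0.576 within and 0.447 between genotypes, a difference of 0.129, and the highest of the other 9 splits gave 0.0248. TP replicate 3 shared 0.470 and 0.455 with TP replicates 1 and 2, which shared 0.511 to 0.534 with TPA replicates 2 and 3. The number of listed peaks and the length they covered were not shown to differ. On the main chromosomes TP libraries had 107315 ± 4404 peaks and TPA libraries 100458 ± 10576 (SD, n = 3, exact permutation p = 0.4). They covered 36.9 ± 10.6 Mb and 35.6 ± 6.66 Mb (SD, n = 3, exact p = 0.7), a difference of -1.30 Mb that became 1.14 without TP replicate 1, 2.36 without TP replicate 2 and 2.47 without TPA replicate 1. The gene-edge share of peaks was 17.8 ± 3.96% and 18.8 ± 3.26% (SD, n = 3, exact p = 0.5), a difference of 0.97 percentage points that became -0.46 without TP replicate 2 and -0.91 without TPA replicate 1. The median peak width was 197 ± 5.77 bp in TP and 170 ± 17.3 bp in TPA (SD, n = 3, exact p = 0.1, the smallest possible), and each TP library was above each TPA library. TP replicate 3 and TPA replicate 1 had narrower wide peaks than the rest, with 95% of their peaks at or under 610 and 930 bp against 1230 to 1550 bp.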

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

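Some alternatives were chosen after seeing the data. They were those without chromosomes 2, 3 and X, without the pair of narrow-peak libraries (TP replicate 3 and TPA replicate 1) and with rank-matched backgrounds. Lists assigned by the nearest gene edge or limited to regions in at least 3 libraries were also among them. So were all alternatives for the gene-edge odds ratio of TP-only against TPA-only regions, the height at gene edges and the chromosomes. Both region counts stayed within 1.5 times their value under 50% overlap, 500 bp windows, the better 50% of each list, equal list length, autosomes only and without chromosomes 2, 3 and X. They left that range with strict presence (2006 TP-only and 1096 TPA-only), at least 2 of 3 libraries (18415 and 13534), at most 1 library of the other genotype (12064 and 7321) and without the narrow-peak pair (16616 and 11123). Leaving out each library gave 8419 to 15560 TP-only and 5186 to 10466 TPA-only regions. TPA-only regions made up 38.1% of both classes and, with each library left out, from 24.998% without TP replicate 3 to 55.4% without TPA replicate 1, the single alternative of those run that put them above 50%; leaving out a library also loosens the presence rule for its genotype. The gene-edge odds ratio of TPA-only against common regions was 2.03 with a width-matched and 1.28 with a rank-matched background; the cause was not tested. Ratios of TP-only against common regions (0.0703 to 0.466) and against TPA-only regions (0.166 to 0.360) stayed below 1 in all 13 alternatives each, though matching the latter on rank could move nothing, since the ranks of both classes were alike. The TPA minus TP difference in the summit contrast at gene edges stayed above 0. It was 0.80 in the better 50% of each list, 0.77 with other regions matched on width, and 0.77 to 1.04 with each library left out. Differences in peak number, covered length and gene-edge share per library cannot pass 0.05 in this design. Leaving out each library, peak number differed by -12858 (without TPA replicate 3) to -2878 (without TPA replicate 1), covered length by -7.40 to 2.47 Mb and gene-edge share by -0.91 to 3.23 percentage points, the latter pair changing sign. No fixed list passed the permutation test in any of 13 alternatives, with 0 to 3 lists per class at an unadjusted p under 0.05; the interferon list's adjusted p for TPA-only regions ran from 0.094 to 0.898. The motif alternatives were not run. The labels share replicate numbers, but same-numbered libraries did not deviate together: correlations of their deviations from the genotype means were -0.04, 0.04 and 0.01. With the replicate number as a block, sign flips within pairs (smallest p 0.25) gave exact p = 0.5 for the difference of -6858 peaks, p = 0.75 for -1.30 Mb and p = 0.75 for 0.97 percentage points of gene-edge share.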

Other observations

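The tests in this part on chromosome 3, on deletions and chromosome dosage in windows, on gene families and transcription factors, on score ranks of the classes, and of the gene-edge ratio between TP-only and TPA-only regions over splits of the libraries were chosen after the results were seen, and those on chromosome 3 were also restated once, when scores were taken relative to the kind of place. The transcription factor families were picked after gene names and counts had been looked at and after the screen of gene families, so that test is not independent of what prompted it. TPA-only regions at gene edges included the edges of developmental transcription factor genes: Emx1, Foxe3, Foxl2, Gata2, Gata5, Gbx1, Gsx1, Hoxc10, Irx1, Irx2, Lhx1, Lhx2, Nkx2-2, Nkx2-6, Sox8 and Zic2. Homeobox, forkhead, SOX, GATA, T-box and ZIC genes accounted for 17 of 726 TPA-only gene-edge regions (2.34%), against 4 of 558 (0.717%) for gene-edge regions with a peak in exactly 3 libraries drawn from both genotypes, an odds ratio of 3.32 (95% interval 1.11 to 9.93, Fisher's exact test, two-sided, p = 0.026). Against the 358 TP-only gene-edge regions, with 4 such, the ratio was 2.12 (0.709 to 6.35, Fisher's exact p = 0.24), so a difference between the genotypes was not shown.

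No gene family passed correction when genes were grouped by symbol stem. Of 311 families with 8 or more genes, tested in both classes (622 tests) by the permutation test on matched random lists, 0 passed an adjusted p of 0.05 and 37 had an unadjusted p under 0.05, where chance gives 31.1. The leading ones were Sox genes, with 20 TPA-only among 277 regions (7.22% against 2.17% in random lists, permutation p = 8.0e-04, adjusted p = 0.498), and Serpina genes, with 8 TP-only among 63 regions (12.7% against 3.17%, permutation p = 0.0022, adjusted p = 0.594). Samd genes came next, with 29 TP-only among 185 regions (15.7% against 3.57%, permutation p = 0.0034, adjusted p = 0.594), of which Samd5 held 24.

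On chromosome 3, with 445 of the TPA-only regions, the median score change of single common regions (TPA minus TP) was positive in 100% of 14 windows of 10 Mb with at least 20 common regions, with window medians of 0.60 to 1.07 on the log2 scale, and 1 of 229 such windows on the other autosomes reached the lowest of these, while 56.8% of those were above 0. By the same measure the change at gene edges, 0.69, was 86.2% of that elsewhere, 0.81, which argues against an effect on distal regions alone, and by the chromosome medians of each library it was 0.70 and 0.68. The difference of chromosome medians, 0.66, kept 94.0% of its size without TP replicate 3 and TPA replicate 1. A candidate explanation is a difference in the number of copies of chromosome 3 between the cultures. Chromosome Y, whose 9 common regions differed by 1.88 but whose 3 at gene edges differed by 0.15, was not tested for it. By the chromosome medians, chromosome 3 stood at -0.50 in TP, with the other autosomes at -0.08 to 0.22 and chromosome X at -0.49. In TPA it stood at 0.16, with the other autosomes at -0.09 to 0.09, so the larger departure was in TP. DNA copy number was not measured here, and a chromosome-wide effect of Arid1a loss stays open. So does any part that copy number may have in Mecom, Muc1 and Car2.

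TP-only regions lay at gene edges less often than TPA-only regions, with an odds ratio of 0.270. A difference in score rank within the lists did not account for it, since the median rank percentile was 44.0 for TP-only and 43.9 for TPA-only regions (difference 0.111, 95% bootstrap interval over regions -0.813 to 1.05), and neither did the narrow-peak libraries (0.333 without them, upper limit 0.365) or chromosomes 2, 3 and X (0.283 without them, upper limit 0.327). Of the 10 splits of the libraries 1, the genotype split, gave a ratio as far from 1, but the next, at 0.271, was close, and 10 splits are too few for a share under 0.05. The smaller side of that next split held only 102 regions and joined the narrow-peak libraries. A loss of distal accessibility in TPA, which the role of BAF complexes at enhancers would lead one to look for, and a difference between library preparations both stay open. For the number of regions, whose comparison with other splits was planned but whose expected outcome was written after the counts were seen, 1 of 10 splits, again the genotype split, gave as many (12601, highest other 2049), with the same limit on the share.

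TP-only regions reached 21 in a window of 500 kb, on chromosome 7 at 110500001 to 111000000, which holds Sbf2, Adm, Ampd3, Rnf141, Lyve1 and Mrvi1. Shuffling the TP-only mark among regions found in 3 or more libraries of the same chromosome reached 21 somewhere in 5.7% of 1000 shuffles. That highest window count may therefore follow from the density of regions. The windows had fixed borders, and the 24 TP-only regions at Samd5, within 411 kb, lay on both sides of such a border. The shuffles thus did not test the clusters at single genes. A deletion of a whole window on all copies is argued against by the common regions present in 5 of the 5 leading windows. At Samd5 and Gas7 the common region inside each stretch of TP-only regions likewise argues against a deletion of that whole stretch on all copies. Smaller deletions and the loss of only some copies stay open, as does a deletion at Cd93, where no region was common and a TPA library had a peak in 3 of 31. Of the 5 windows, 4 lay on chromosomes 6, 7 and 17, whose score shift was inside the range of the other autosomes. That range took in chromosome 3 (0.74), so lying inside it decides little. The median change of single common regions, TPA minus TP, was 0.11 on chromosome 6, 0.02 on 7 and 0.15 on 17. Values not below 0 argue against a lower dosage of these whole chromosomes in TPA. Dosage stays open for the window on chromosome 2, where the change was -0.19.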
